A study of Mus musculus with 2 samples.

How the data were processed

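Whole testis of C57BL/6 mice at 13 days of age was profiled with 10x 3' V3 single-cell libraries, 1 from a control (Psma7 F/+) and 1 from a conditional knockout (Psma7 F/-;Stra8-Cre KI/+). The deposited values are raw UMI counts for each gene and barcode, which the authors made with Cell Ranger 7.1.0, per the file headers, on mm10, per the labels. The matrices are unfiltered, so cells had not been called. They list 1707157 barcodes in the control and 1477364 in the knockout library, with 32285 genes and totals of 146528736 and 112746953 UMIs. Of the gene identifiers, 32235 were found in GENCODE M21, which gave the coordinates.

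A barcode counted as a cell with at least 1000 UMIs and 500 genes, which 12463 barcodes of the control and 11995 of the knockout library had, and at most 20% mitochondrial UMIs, which left 11232 and 10864. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 1 cell of the knockout library, under the 0.5% taken as a sign that the call had not worked, so the control's threshold was used for both, a choice made after seeing the data. It removed 490 cells (4.36%) and 266 cells (2.45%). The cells left, 10742 and 10598, held 115923847 and 91049809 UMIs. They were scaled to 10000 UMIs, log transformed, reduced to 2000 highly variable genes and 30 principal components, and clustered together with 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2), without alignment of the libraries. This gave 29 clusters.

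A cluster could take the name of 1 of 14 classes from marker genes fixed beforehand when at least 3 markers were at least 1.5-fold above all other cells and seen in at least 20% of its cells. Of such classes it took the one with the highest mean standardised marker level. It lost the name if its 10 leading genes held more markers of another class, or if it had few UMIs and no marker of its class among those genes. A clash between germ cell stages left it in the widest germ class that held both. These last details were settled after seeing the data. Names describe resemblance to a class by its transcripts. Classes with fewer than 50 cells in a library, early meiotic cells among them, entered only the composition and the level of Psma7.

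For each class with at least 50 cells in both libraries, UMIs were summed per library and divided by the class total (CPM). The log2 ratio of knockout over control had 0.5 added to each count. Levels have exact 95% Poisson intervals, ratios exact conditional intervals and shares exact 95% Clopper-Pearson intervals (scipy 1.17.1), and a count of 0 was given the limit of 3 counts. For each of 24 gene lists the median log2 ratio was taken over members with at least 30 UMIs and set against 10000 random lists of the same size, each member replaced by a draw from the 100 measured genes nearest to it in expression. With 1 library per group no test between genotypes was made, and cells and genes were not used as replicates of a genotype. Members of 1 list, the p53 targets, were resampled, which gives a spread over genes and not between animals. The intervals and lists were tested on simulated data, Poisson counts drawn from the pooled profile of a class at the depth of each library with 200 genes changed. In undifferentiated spermatogonia the intervals held the truth for 95.6% of unchanged genes and 94.0% of genes changed 2-fold, in Sertoli cells for 95.7% and 96.0%. Of 100 unchanged lists, 3 and 4 fell outside the random range. Those lists were random genes, and the simulated counts held no difference between suspensions. They do not show how often genes regulated together leave the range without an effect of genotype.

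Genes named in the text are Psma7, the markers of a class, the 2 highest and 2 lowest members of each list, and for spermatogonia, their undifferentiated and differentiating classes and Sertoli cells the 10 highest and 10 lowest ratios among genes with at least 20 CPM and 30 UMIs in the higher library. Mitochondrial, ribosomal and haemoglobin genes, unnamed gene models and genes that free RNA at 10% would account for were left out of that ranking. Free RNA was read from barcodes with 10 to 100 UMIs. The lists, markers, the rule for genes named in the text, comparisons and most alternatives were fixed before the data were examined; the rule for naming clusters was fixed only in part, as said above. The p53 and proteasome results in undifferentiated spermatogonia, the G2 and mitosis and niche results in Sertoli cells and the separate somatic shares were raised to main results after it.

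The alternatives were minimums of 500 UMIs and 250 genes or 2000 UMIs and 1000 genes, at most 10% mitochondrial UMIs, doublets kept, resolution 2, each library clustered alone, stress, cell cycle and proteasome genes left out of the clustering, at least 100 UMIs per gene, ratios centred on the median gene, and 10% of the UMIs subtracted as free RNA. Chosen after seeing the data were the automatic doublet threshold in each library, free RNA from barcodes with more than 100 and up to 250 UMIs, free RNA at the share measured in each class and library from Amh, Cst9, Cst12 and Aard, or outside germ cells Tex101, Sycp3, Hormad1 and Prss50 (the lower where both applied), differentiating spermatogonia without their cluster of cells with few UMIs, and Sertoli cells without the cluster led by cell cycle genes. Other software was anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 on Python 3.11.15.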

Results

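The series holds single-cell RNA profiles of whole testis from C57BL/6 mice at 13 days of age. By that age the first wave of spermatogenesis has reached meiosis. There were 2 libraries, 1 per genotype. The control carried a floxed and a wild-type copy of Psma7 (F/+), and the conditional knockout carried a floxed and a deleted copy together with Stra8-Cre (F/-;Stra8-Cre KI/+), a Cre that acts in germ cells and that the control's label does not give. Psma7 encodes α4, a subunit of the constitutive 20S proteasome, and the series asks what that proteasome does for spermatogonia. The control library held 146528736 UMIs and gave 10742 cells, with a median of 8042.5 UMIs and 3442 genes per cell. The knockout library held 112746953 UMIs and gave 10598 cells, with a median of 5393.5 UMIs and 2665.5 genes. How many animals went into each library is not given. Since each genotype has 1 library, no difference below has a replicate check or a test, and every 95% interval covers counting error only. Levels are counts per total UMIs in CPM, summed over the cells of a class, and log2 ratios are knockout over control.

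Psma7 itself came first, as a check of the labels. Psma7 (ENSMUSG00000027566) lies on chromosome 2 of mm10 at 180036374 to 180042433, on the minus strand. In germ cells its level was 221 CPM in the control (interval 217 to 225) and 84.3 CPM in the knockout library (77.0 to 92.0), a log2 ratio of -1.39 (-1.52 to -1.26). The median gene measured in germ cells of both libraries stood at 0.21, and relative to it Psma7 was at -1.60. Germ cells of the control included 1349 early meiotic cells, with Psma7 at 97.2 CPM, a class without cells in the knockout library. In spermatogonia alone Psma7 was at 288.8 and 84.3 CPM, a log2 ratio of -1.78 (-1.91 to -1.65) and 29.2% of the control level. The undifferentiated spermatogonia of the knockout library held 94.1 CPM against 246 in the control, or 38.3% of the control level. The differentiating spermatogonia held 52.0 CPM against 300.3, a log2 ratio of -2.52 (-2.89 to -2.19) and 17.3% of the control level. Psma7 was lower in the knockout library in somatic cells too, where Stra8-Cre is not meant to act but where the genotype label (F/-) gives every cell a null copy. It stood at 98.6 CPM against 240.3 over all of them, 41.0% of the control level. Sertoli cells, the somatic cells of the tubule, were at -1.45 on the log2 scale, peritubular myoid cells at -1.27, interstitial stromal cells at -1.18, endothelial cells at -1.12, Leydig cells at -1.08 and macrophages at -1.05. Of the small classes, rete or mesothelial epithelium was at -1.62. Pericytes, 42 and 25 cells, were at -0.50, with an interval from -1.18 to 0.13 that includes no change. Which exons are floxed is not given. The 3' tag that was counted may lie outside the deleted part, in which case these values count transcripts made from the locus and not intact ones.

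**Figure D1:**
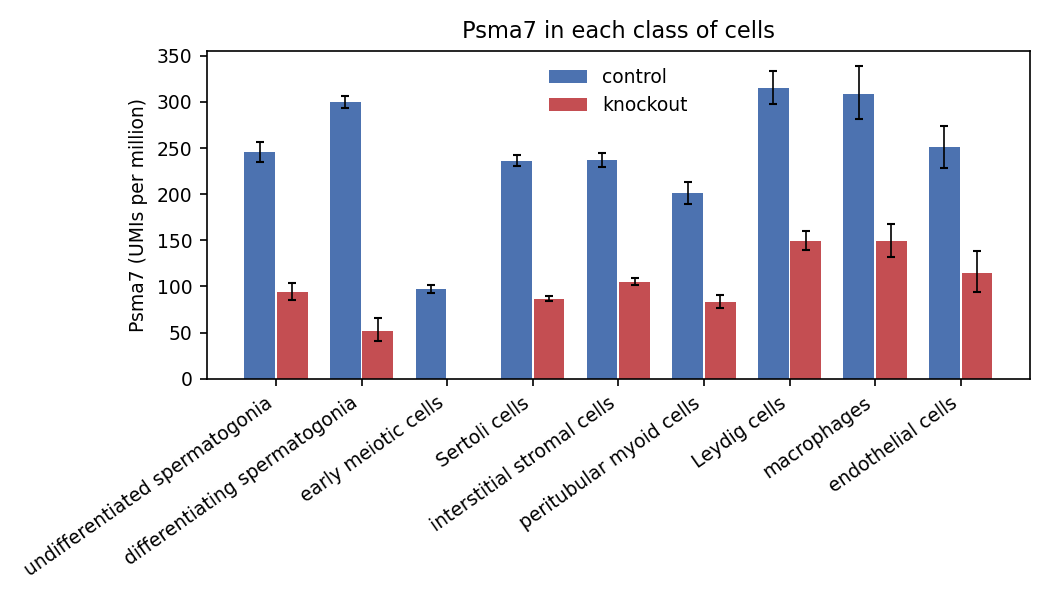
Psma7 level in CPM (y axis) in each class of cells (x axis), for the control library (blue) and the knockout library (red), with exact 95% Poisson intervals as error bars. The knockout bar is lower in every class drawn for both libraries, and lowest in differentiating spermatogonia at 52.0 CPM; early meiotic cells have no knockout bar because no cell of that class was found there.

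The second comparison asked which germ cells the testis holds without a full Psma7 dose. Germ cells were far scarcer in the knockout library, and the later the stage, the larger the gap. They made up 3782 of 10742 cells in the control (35.2%, interval 34.3 to 36.1) and 401 of 10598 in the knockout library (3.78%, 3.43 to 4.16). Set against Sertoli cells, there were 98.4 germ cells per 100 Sertoli cells in the control and 6.14 in the knockout library, 16.0-fold lower (14.3 to 17.9). Undifferentiated spermatogonia, the class that holds the stem cells, were 515 beside 3845 Sertoli cells in the control and 293 beside 6534 in the knockout library. Differentiating spermatogonia, marked by Kit and Sohlh1, were 1918 and 108. Cells at the entry into meiosis, marked by Stra8 and Meioc, were 1349 in the control and 0 in the knockout library.

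Among germ cells, spermatogonia were 64.3% in the control (62.8 to 65.9) and 100% in the knockout library, where 0 spermatocytes among 401 germ cells allow a share of up to 0.916%. Among spermatogonia, the undifferentiated share was 21.2% in the control (19.6 to 22.8) and 73.1% in the knockout library (68.4 to 77.3). No cluster in either library had the markers of zygotene to pachytene spermatocytes as its main ones. With each library clustered alone, all spermatogonia of the knockout library fell into the undifferentiated class, so that share became 100%. With stress, cell cycle and proteasome genes left out of the clustering, spermatogonia were 39.8% of control germ cells and spermatocytes 23.9%, since 36.3% were left without a stage, and the spermatogonial share of the knockout library was 99.0%.

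**Figure D2:**
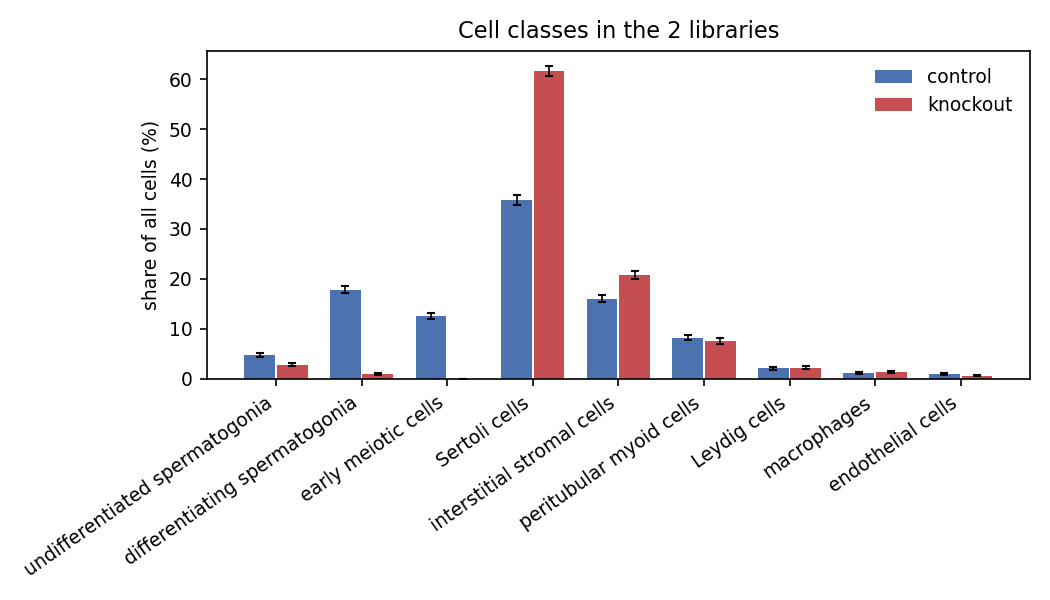
Share of all cells, in percent (y axis), in each of the 9 classes with at least 50 cells in a library (x axis), for the control (blue) and the knockout library (red), with exact 95% Clopper-Pearson intervals. The 3 germ cell classes are lower in the knockout library, early meiotic cells at 0 of 10598, while Sertoli cells go from 35.8% to 61.7%.

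Levels over all cells, which do not depend on clusters, were lower in the knockout library for most markers of the later stages, with intervals below 0 for 13 of 14 markers of differentiating spermatogonia, 14 of 15 of meiotic entry and 14 of 18 of spermatocytes. Stra8, which germ cells need for entry into meiosis, was at 229.6 CPM in the control and 6.41 CPM in the knockout library; the labels give the Cre as a knock-in under its name, so its own level may reflect that allele as well. Meioc, another gene of meiotic entry, was at 129 and 1.77 CPM. Sycp1, which builds the synaptonemal complex, was at 435 and 26.5 CPM. The differentiating markers Dmrtb1 and Rhox13 were at 19.3 and 0.571 CPM and at 58.3 and 1.77 CPM. Prss50 and Esx1, also of that stage, were at 122 and 0.110 CPM and at 75.2 and 0.406 CPM. Kit was closer between the libraries, at 68.0 and 22.6 CPM. The 18 markers of undifferentiated spermatogonia went both ways, 10 lower, among them Lin28a at -2.36 and Sall4 at -1.86, 5 higher, among them Id4 at 0.90 and Etv5 at 0.87, and 3 within counting error, among them Gfra1, the GDNF receptor, at 19.8 and 20.0 CPM. Of the markers of later stages, 5 were higher in the knockout library. Rad51ap2, in the meiotic list, was at 49.3 against 40.6 CPM, a log2 ratio of 0.28 that was -0.21 with at most 10% mitochondrial UMIs. Ccnd2 was at 1.02, Insl6 at 0.59, Hspa2 at 0.38 and Ldhc at 0.38, or -0.14 with that limit. Levels over all cells include somatic ones, and Ccnd2 was at 118 and 193 CPM in Sertoli cells.

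The third comparison asked how the spermatogonia that were present differed. The undifferentiated class, a single cluster shared by both libraries (515 and 293 cells, medians of 13265 and 13138 UMIs), gave the closest match of stage. Read from Sertoli cell genes, free RNA made up at most 2.97% of its UMIs in the control and 3.38% in the knockout library, and 3.14% and 3.81% in differentiating spermatogonia, so the planned subtraction of 10% takes off more than was measured. Its p53 targets were higher in the knockout library: 17 of 20 measured members, with a list median of 0.40 against a 95% range of -0.16 to 0.19 for 10000 random lists matched on expression. The median was 0.25 over genes with at least 100 UMIs, and 0.22 without Btg2, Plk2 and Gadd45a, which handling induces, both close to ranges that ended at 0.21. Cdkn1a, an inhibitor of the cell cycle, rested on 30 and 87 UMIs and was at 3.91 CPM in the control and 19.3 CPM in the knockout library, a log2 ratio of 2.29 (1.69 to 2.96). Eda2r, a receptor of the TNF family, stood at 1.92. Fas was at -0.99, with an interval from -2.52 to 0.19, and Trp53 itself at -0.15.

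The other subunits of the proteasome were slightly higher, in 27 of 32 cases, with a median of 0.19 against a random range of -0.12 to 0.08. Psmc2 and Psmc1, ATPases of the 19S particle, led at 0.63 and 0.52, while Psmd13 and Psma2 were at -0.15 and -0.05. Over all spermatogonia, where the mix of stages differs, the same list had a median of -0.03 and a mean of 0.01, inside its random range of -0.20 to 0.06. Special subunits, activators and assembly factors went both ways, with a median of 0.02 and a mean of -0.11: the assembly factor Pomp was at 0.57 and Psmd5 at 0.33, while the immunoproteasome subunits Psmb10 and Psmb9 were at -1.16 and -0.99. Ubiquitin and proteasome stress genes had a median of 0.07, led by Ubqln2 at 1.27 and Zfand2a at 0.76. Autophagy genes had a median of 0.01, with the cargo receptors Sqstm1 and Optn at 1.16 and 1.14 and Map1lc3b at -0.52. All 17 measured heat shock genes were higher, but their median of 0.16 lay inside the random range, which ended at 0.19; Hspb1 was at 1.27 and Hspa1b, nearly identical in sequence to Hspa1a, at 0.62, though 0 of its UMIs were left in the knockout library once 10% of the UMIs were subtracted as free RNA, and at the measured share it was at 0.26. The unfolded protein and integrated stress response had a median of 0.14, also inside its range, with Atf3 at 1.70, Sesn2 at 1.23 and Trib3 at -1.14. Oxidative stress genes stood above their range with a median of 0.37, 15 of 18 higher, led by Nqo1 at 1.32 and Gpx1 at 0.73. Apoptosis genes had a median of 0.10, with Bmf at -0.66.

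Genes of the differentiating stage were lower within this class. The differentiating programme had a median of -0.46 (random range -0.19 to 0.26), with 10 of 14 members lower, led by Prss50 at -2.93 and Esx1 at -2.41, while Ccnd2 was at 0.68. With 10% free RNA subtracted, 0 UMIs of Prss50 were left in the control, and at the measured share it was at -1.48. The meiotic entry programme had a median of -0.20, just below its range, with Stra8 at -1.15 and Spo11 at -0.92, and was at -0.03, inside it, with 10% free RNA subtracted and at -0.08, also inside, at the measured share. Spermatocyte genes had a median of -0.11 and a mean of 0.02, inside the range. In the retinoic acid pathway, the signal that drives differentiation, the median was -0.37, with the receptor Rarg at -1.50 and Crabp1 at -1.25, against Aldh1a1 at 1.32; with each library clustered alone that median was 0.04. The undifferentiated programme itself split, with a median of 0.19 inside its range and a mean of -0.06. Lhx1 was at 1.78 and Nanos2 at 1.23, and Upp1 and Utf1 were at -3.02 and -1.82. G2 and mitosis genes were higher (median 0.27, 21 of 26, Mki67 at 0.84 and Ccnb2 at 0.81), and S phase genes had a median of 0.16, just above a range that ended at 0.15, with Ccne1 at 1.16, but 0.11 and inside with the automatic doublet threshold. DNA damage and recombination genes had a median of -0.09 and a mean of 0.05, and Ccnb1ip1 was at 1.69. Inflammation and interferon genes had a median of -0.25, from 9 measured members, with Oasl2 at -1.14, and -0.03, inside the range, with each library clustered alone. Mitochondrially encoded genes had a median of -0.21 and nuclear genes of oxidative phosphorylation one of 0.04.

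Immediate-early genes of the dissociation response were higher in this class as well, all 18 of them, with a median of 0.93 and Ier3 at 1.49. With 10% free RNA subtracted that median was 0.23, inside its range, and at the measured share 0.54, above it. Sertoli cell genes had a median of 0.84, with Amh at 2.93, on levels of 1.17 and 9.34 CPM, and free RNA of the knockout library also held more of them. Niche and junction genes had a median of 0.12, or -0.38 with 10% free RNA subtracted, and steroid synthesis genes 0.05.

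By size of the ratio, Cib4 (4.21), Slamf1 (3.62), Ckmt2 (3.28), Rdh12 (2.84), Duox1 (2.78), Ppp1r36 (2.39), Xaf1 (2.31), Phkg1 (2.17), Stpg4 (2.17) and Nefm (2.10) were the genes furthest above the control in undifferentiated spermatogonia. The furthest below were Upp1 (-3.02), Fli1 (-3.00), Sorcs3 (-2.88), Phlda2 (-2.43), Epb41l4a (-1.97), Mctp1 (-1.97), Palm (-1.97), Cdk6 (-1.97), Fras1 (-1.92) and Apba2 (-1.81). Cdk6, a kinase of the G1 phase, went from 115 to 29.4 CPM. Over all spermatogonia the ratios also carry the shift of stage: Barhl2 (3.80), Nefm (3.57), Lgi1 (3.54) and Lhx1 (3.26) were highest, and Prss50 (-5.62), Esx1 (-4.52), Gli2 (-3.20) and Sgcb (-3.01) lowest. Free RNA and handling were not separated from genotype by the design, since each genotype was a separate suspension.

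The differentiating spermatogonia that remained in the knockout library, 108 cells against 1918, had higher levels of the undifferentiated programme, but also of Sertoli cell and dissociation genes. All 17 measured genes of the undifferentiated programme were higher, with a median of 1.35 (random range -0.10 to 0.70), led by Tspan8 at 2.81. The Sertoli programme had a median of 1.29 (17 of 18 higher), niche and junction genes 1.09 and the dissociation response 0.91 (16 of 18), all above their ranges. Without the cluster of cells with few UMIs these were 1.03, 1.13 and 0.92, and the undifferentiated programme was at 0.91, against a range that ended at 0.77. With 10% free RNA subtracted, the niche and dissociation medians were 0.16, inside its range, and -0.68, below its range, while the undifferentiated programme was at 1.58; the Sertoli programme gave no value there, and was at 0.39, inside its range, with doublets kept. At the measured share of free RNA the Sertoli, niche and dissociation medians were 0.52, 0.96 and 0.37, the niche median alone above its range, and the undifferentiated programme was at 1.41. Prss50 and Esx1 were at -4.72 and -3.21. The meiotic entry programme had a median of -0.31, with Meioc at -1.75 and Prdm9 at -1.64. Replication and division genes were lower, at medians of -0.33 for S phase (22 of 24 lower) and -0.27 for G2 and mitosis (20 of 26 lower), with Ccne2 at -0.80, Plk1 at -1.18 and Mki67 at -0.61. With stress, cell cycle and proteasome genes left out of the clustering, the S phase median was -0.14, inside its range, and the G2 and mitosis median 0.15, Mki67 was at 0.36, Meioc at 0.28 and Dpep3 at 0.04. The other proteasome subunits had a median of 0.16 (random range -0.25 to 0.02), with Psmd7 at 0.88 and Psmb6 at 0.60. Here the special subunits and assembly factors had a median of 0.38, and Psmb10, lower in the undifferentiated class, was at 1.30. The p53 targets had a median of 0.20, inside a range that ended at 0.23, with Eda2r at 2.42 and Pmaip1 at 1.79; without the cluster of cells with few UMIs it was 0.38, above its range, as were 0.33 with doublets kept and 0.30 with 10% free RNA subtracted. Most control cells of this class lay in clusters 10 and 12 (919 and 769 cells), whereas most knockout cells lay in clusters 21 and 12 (57 and 47 cells). Cluster 10, with Esx1 and Dmrtb1 among its leading genes, held 4 knockout cells. The ratios of this class therefore compare different mixes of clusters and may also carry a shift of stage. Cluster 21 held cells with few UMIs, a median of 1904 in the control and 1693 in the knockout library.

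The genes furthest above the control in this class were Nkx6-3 (7.38, on 5 and 43 UMIs), Stx19 (5.54), Lgi1 (5.27), Trpm5 (4.51), Kcnh7 (4.50), Adam32 (4.43), Dusp27 (4.33), Hkdc1 (3.95), Samsn1 (3.67) and P2rx4 (3.64). After Prss50, those furthest below were BC051142 (-4.28, on 613 UMIs and 1 UMI), Esx1, Ly6k (-3.04), E2f2 (-2.83), Psma7 itself, Sgcb (-2.49), Zc3hav1 (-2.12), Hs6st2 (-1.93) and Dpep3 (-1.92).

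The fourth comparison concerned Sertoli cells, which nurse the germ cells and in which the Cre is not meant to act. Those of the knockout library carry a null copy of Psma7 by the label, with Psma7 at 36.6% of the control level. In the knockout library they had more transcripts of mitosis, of the niche factor Gdnf and of Amh, an immature Sertoli cell hormone. Amh was at 61.8 CPM in the control and 287 CPM in the knockout library, a log2 ratio of 2.21 (2.14 to 2.29). Gdnf, which maintains spermatogonial stem cells, was at 23.1 CPM in the control, with a log2 ratio of 2.04 (1.92 to 2.16). Of the G2 and mitosis genes 25 of 26 were higher, with a median of 1.39 against a random range of -0.10 to 0.24, led by Ube2c at 2.29 and Cdc25c at 2.24, with Bub1 at -0.26, or 0.47 with doublets kept. S phase genes did not move with them (median 0.02, with Slbp at 0.88 and Hells at -0.56). With 10% free RNA subtracted they did, at a median of 0.98, and Hells was at 1.11. Free RNA read from early meiotic genes made up at most 8.16% of the UMIs of control Sertoli cells and 17.6% of those of the knockout library, and taken off at these unequal shares it left medians of 3.09 for G2 and mitosis and 0.41 for S phase, just above a range that ended at 0.39, with Gdnf at 2.10. The share of 17.6% is uncertain, as free RNA of the knockout library held only 26.8 CPM of these genes. In its peritubular myoid cells they gave 19.4% where Sertoli cell genes gave 7.26%, and in Leydig cells 5.68% against 7.36%. Values below at the measured shares may therefore subtract too much from knockout Sertoli cells. Without the cluster led by cell cycle genes, 11 control and 355 knockout cells, the G2 and mitosis median was -0.01, the S phase median -0.17, below its range, and Knl1 was at -0.07.

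The niche factor and junction list had a median of 0.35 (random range -0.24 to 0.23), with Inhba at 1.87 beside Gdnf, while the junction genes Cdh2 and Cldn11 were at -0.81 and -0.56; at the measured shares of free RNA that median was -0.00, inside its range. The Sertoli programme as a whole had a median of 0.07 and a mean of -0.06, with Amh and Dhh (0.67) on one side and the X-linked genes Tsx (-2.47) and Rhox5 (-1.27) on the other. Steroid synthesis genes had a median of 0.56, led by Hsd17b1 at 2.46, with Scarb1 at -0.64, but 0.13 and inside the range with 10% free RNA subtracted. In the retinoic acid pathway the median was -0.29, or -0.18 and inside the range with free RNA read from barcodes of up to 250 UMIs, and Cyp26b1, which degrades retinoic acid, was at 1.25. Subtracting 10% of the UMIs as free RNA left 0 UMIs of Inhba and Cyp26b1 in both libraries, so neither ratio stands apart from free RNA. Proteasome genes had a median of -0.07 and special subunits -0.05, both inside their ranges, as were ubiquitin genes (median -0.00, mean 0.08, Nfe2l1 at 0.82), p53 targets (0.03, Cdkn1a at -0.89), apoptosis (-0.07), autophagy (-0.07), DNA damage and recombination (-0.03), inflammation (0.27), mitochondrially encoded genes (0.15) and nuclear oxidative phosphorylation (0.02). Heat shock genes had a median of 0.38, with Hspa1b at 1.08 and Dnajb1 at 1.05, the unfolded protein response 0.19, with Dnajb9 at 1.05, and oxidative stress 0.20, with Nqo1 at 0.64. With at most 10% mitochondrial UMIs the last 2 were inside their ranges, at 0.14 and 0.11, and the proteasome median was 0.11, above its own. At the measured shares of free RNA the heat shock and oxidative stress medians were inside their ranges, at 0.09 and -0.00, and the proteasome median was below its own, at -0.25. Dissociation response genes were higher in 17 of 18 cases, with a median of 0.99. The germ cell lists had medians of -0.13 for the undifferentiated, -2.70 for the differentiating, -2.67 for the meiotic entry and -1.55 for the spermatocyte programme; the last 3 were above 0 once 10% of the UMIs were subtracted as free RNA, and at -0.59, -0.18 and -0.01 at the measured shares.

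**Figure D3:**
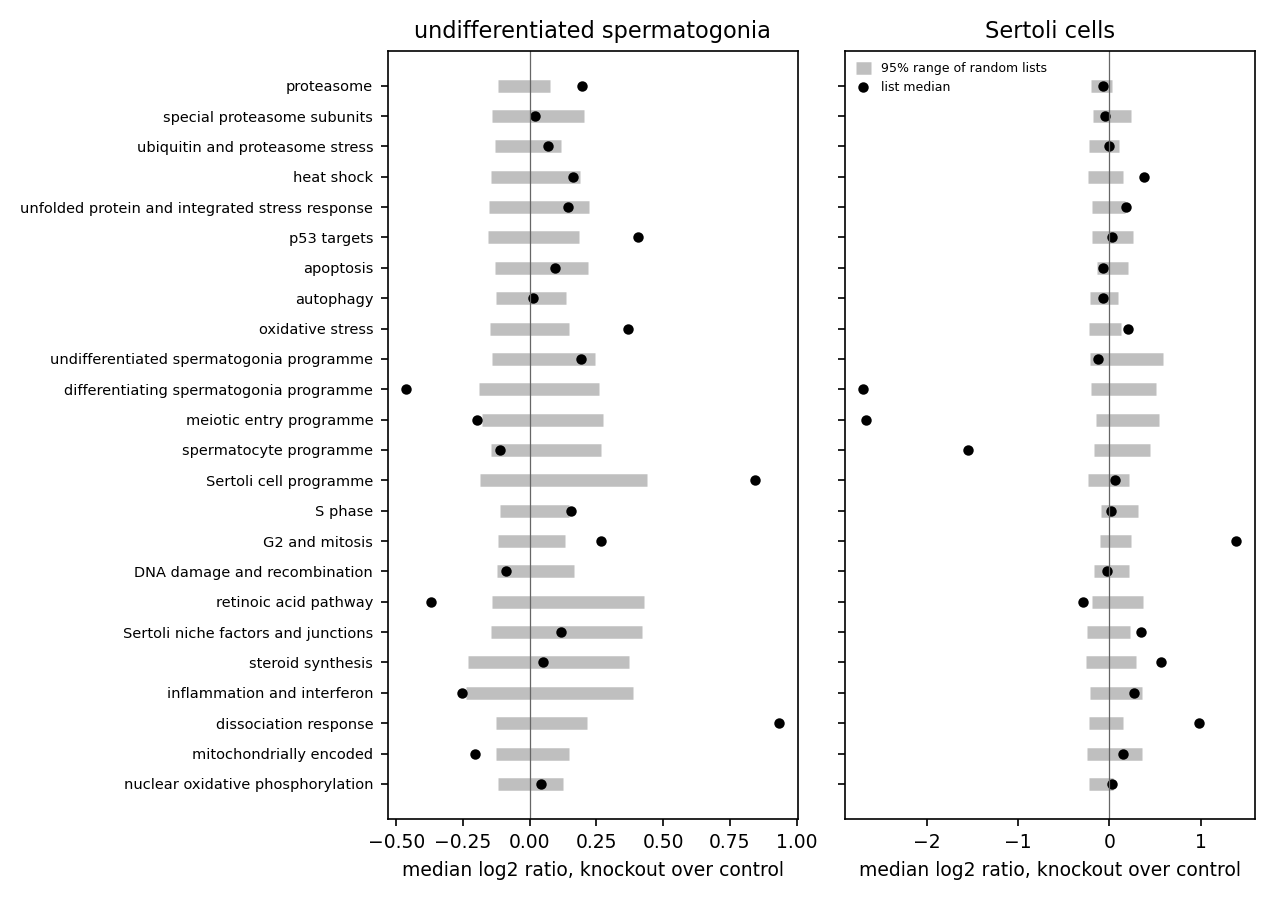
Median log2 ratio of each of the 24 gene lists, knockout over control (x axis), in undifferentiated spermatogonia (left) and Sertoli cells (right). Points are list medians and grey bars the 95% range of 10000 random lists matched on expression. The p53 targets stand above the bar at 0.40 on the left only. G2 and mitosis genes stand above it on both sides, at 0.27 on the left and 1.39 on the right.

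By size, Rimbp2 (3.98), Epha5 (3.20), Smad6 (2.87), Rtn4rl1 (2.67), Hsd17b1, Pcdh17 (2.30), Ube2c, Knl1 (2.29), Ccnb1ip1 (2.23) and Pcdh15 (2.23) were furthest above the control in Sertoli cells. Sdk2 (-2.99), Samd12 (-2.77), Rubcnl (-2.75), Lhfp (-2.52), Tsx, Cpne8 (-2.43), Sulf1 (-2.18), Hopx (-2.17), Sncb (-2.16) and B4galt6 (-2.16) were furthest below. Control Sertoli cells lay mostly in clusters 2, 5 and 8 (1101, 1217 and 701 cells) and knockout ones mostly in clusters 1, 4, 7 and 9 (1525, 1241, 1109 and 924 cells), so these values compare largely separate clusters of the same class.

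The last comparison took each somatic class as a share of all somatic cells, 6942 in the control and 10002 in the knockout library. Sertoli cells were 55.4% in the control (54.2 to 56.6) and 65.3% in the knockout library (64.4 to 66.3). That difference of 9.94 points was 5.16 points with at most 10% mitochondrial UMIs. Peritubular myoid cells, the contractile wall of the tubule, were 12.7% (11.9 to 13.5) and 7.99% (7.46 to 8.54). Interstitial stromal cells were 24.8% and 22.0%, a difference of -2.80 points that became 1.44 points when cells were limited to 10% mitochondrial UMIs. Leydig cells, which make androgen, were 3.20% and 2.28%, and with each library clustered alone 3.85% and 1.77%. Macrophages were 1.76% and 1.32%, endothelial cells 1.31% and 0.650%, pericytes 0.605% and 0.250% (0% and 0.273% with each library clustered alone), and rete or mesothelial epithelium 0.230% and 0.140%. A cluster of cells with few UMIs that stayed unnamed held 18 cells in the control (0.168% of all cells) and 195 in the knockout library (1.84%). Shares depend on how well each class survives dissociation, which could not be checked.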

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

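Of the tests here, those on free RNA, at the planned 10% and at the measured share, on damaged cells and on handling were chosen after the result was seen, and so was the resampling of the p53 list; the other 2 were written before.

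Several gene lists moved one way in undifferentiated spermatogonia and the other way in a somatic class, with both medians outside their random ranges; the difference between classes was not tested. The other proteasome subunits, at 0.19 in undifferentiated spermatogonia, had medians of -0.11 in Leydig cells, -0.25 in peritubular myoid cells and -0.10 in interstitial stromal cells, the first and last inside their ranges, at -0.08 and -0.07, once 10% free RNA was subtracted, though not at the measured shares. The p53 targets, at 0.40 in undifferentiated spermatogonia, were at -0.20 in stromal cells. Oxidative stress genes, at 0.37, were at -0.20 in peritubular myoid cells, or -0.16 and inside the range with doublets kept. S phase genes, at 0.16, were at -0.34 in Leydig cells and -0.33 in peritubular myoid cells, though at 0.07 and 0.05 once 10% free RNA was subtracted, and at -0.14 and -0.16, inside their ranges, at the measured shares, and G2 and mitosis genes, at 0.27, were at -0.39 in peritubular myoid cells, or -0.05 with doublets kept. Inflammation and interferon genes, at -0.25, were at 0.12 in stromal cells, or 0.06 with 10% free RNA subtracted, and 0.20 in macrophages. Mitochondrially encoded genes, at -0.21, were at 0.33 in endothelial cells.

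The p53 targets of undifferentiated spermatogonia (median 0.40) were weighed against 3 technical or compositional explanations. Subtracting 10% free RNA left the median at 0.60, and the measured shares, 2.97% and 3.38%, at 0.57, both above its value without subtraction, which argues against free RNA. In the control, undifferentiated over differentiating spermatogonia gave a median of -0.14 (random range -0.25 to 0.45). That contrast is between classes, and its range ended above 0.40, so the bound written for it was too wide and a less advanced stage of the cells within the class stays open. Without Btg2, Plk2 and Gadd45a, which handling induces, the median was 0.22, against a range that ended at 0.21, and resampling its 17 members gave 0.01 to 1.54, so a part played by handling stays open. A p53 response to the loss of Psma7 may also underlie it, or one to the Cre, which only the knockout library carries by its label; the single library per genotype leaves both untested. Psma7 was at 38.3% of the control level in these cells and at 36.6% in Sertoli cells, where the p53 median was 0.03, inside its range.

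The G2 and mitosis genes of Sertoli cells (median 1.39) stood at 3.68 after subtraction of 10% free RNA, at 3.09 after that of the measured shares and at 1.86 with at most 10% mitochondrial UMIs, against random ranges that ended at 0.36, 0.32 and 0.22. These values argue against free RNA and damaged cells as the whole cause. A larger share of dividing Sertoli cells may explain it. The cluster led by cell cycle genes held 11 of 3845 Sertoli cells in the control and 355 of 6534 in the knockout library. The cluster was picked by its level of these same genes, so the counts are no separate test, and none was made. The median of -0.01 without that cluster follows from the removal of the cells richest in those genes. The S phase median of all Sertoli cells was 0.02, or 0.98 with 10% free RNA subtracted, and -0.17, below its range, without that cluster. Whether a larger share of dividing cells follows from genotype or differs between animals cannot be read from 1 library each.

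Dissociation response genes lay above their random range in 6 of the 8 classes of cells, germ and somatic. In undifferentiated spermatogonia the median fell inside its range, at 0.23, with 10% free RNA subtracted, and in differentiating spermatogonia below it, at -0.68. At the measured shares, 2.97% and 3.38% in the first and 3.14% and 3.81% in the second, the medians were 0.54, above its range, and 0.37, inside. Handling of the suspension is a candidate explanation, and it cannot be told apart from genotype, since each genotype was a separate suspension.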

How the results depend on the processing

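The alternatives with the automatic doublet threshold, with free RNA from barcodes of up to 250 UMIs, with free RNA at the measured share, and without a cluster were chosen after the result was seen. No paired analysis was possible because each genotype has 1 library and nothing links the animals. Of 152 values for the 15 main results under the alternatives, 121 stayed within the interval of the reported value, 28 moved beyond it and 3 changed direction; of 4090 for the 315 others, 3750 stayed, 296 moved and 44 changed direction. The germ cell share stayed between -32.2 and -31.3 points, the p53 median between 0.25, at 100 UMIs per gene, and 0.64 and the niche median in Sertoli cells between -0.0018 and 0.37. Clustered alone, the knockout library gave no differentiating class, so its lists have no value there. Except where stated, the cause was not tested.

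The share of spermatogonia among germ cells, 35.7 points higher in the knockout library, and that of spermatocytes became 27.1 and -27.1 points at 500 UMIs and 250 genes, 33.6 and -33.6 at 2000 UMIs and 1000 genes, 27.2 and -27.2 with doublets kept, 33.0 and -33.0 both at resolution 2 and with libraries clustered alone, and 59.2 and -23.9 with stress, cycle and proteasome genes left out, where the undifferentiated share of spermatogonia was 39.2 points higher. Clustered alone, that share was 78.7 points higher, Sertoli and Leydig shares differed by 12.4 and -2.08 points, pericytes by 0.273, and the undifferentiated medians were 0.32 for the proteasome and 0.042 for the retinoic acid pathway. At most 10% mitochondrial UMIs gave a germ to Sertoli ratio of 0.0749 of the control's, Sertoli and stromal shares of 5.16 and 1.44 points, and a G2 and mitosis median of 1.86 in Sertoli cells, which was 1.62 with doublets kept. Resolution 2 gave a stromal share of -1.49 points. Centring gave Psma7 in germ cells -1.60, which follows from the shift of the median gene.

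Subtracting 10% free RNA gave medians of 0.60 for p53 targets in undifferentiated spermatogonia, 3.68 for G2 and mitosis in Sertoli cells, and there 0.20, 0.80 and 1.22 for the differentiating, meiotic entry and spermatocyte programmes. With barcodes of more than 100 and up to 250 UMIs these were 0.64, 3.53, 0.18, 0.57 and 1.07. At the share measured in each class, an upper limit, the G2 and mitosis and niche medians in Sertoli cells were 3.09 and -0.0018. Without the cluster led by cell cycle genes, the G2 and mitosis median was -0.0084, since those cells carry the list.

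Named genes and lists that changed direction were the following. At most 10% mitochondrial UMIs put Rad51ap2 and Ldhc over all cells at -0.21 and -0.14 and Bub1 in Sertoli cells at 0.21. With doublets kept, Bub1 was at 0.47, and in stromal cells Cenpe was at -0.22 and the S phase and G2 and mitosis medians at -0.010 and -0.22. With stress, cycle and proteasome genes left out of the clustering, differentiating spermatogonia had Dpep3 at 0.043, Meioc at 0.28, Mki67 at 0.36 and a G2 and mitosis median of 0.15. Subtracting 10% free RNA put Hspa1b and Prss50 in undifferentiated spermatogonia at -5.56 and 3.58. No UMIs were left of Hspa1b in the knockout library and of Prss50 in the control, so the added 0.5 sets the size of both. In Sertoli cells Hells was at 1.11, Bub1 at 2.92 and both Cyp26b1 and Inhba at -0.43, which comes from the added 0.5 since no UMIs of them were left. S phase medians were 0.068 in Leydig cells and 0.049 in peritubular myoid cells, and the dissociation median was -0.68 in differentiating spermatogonia. With the other barcodes, Hspa1b and Prss50 were at -6.00 and 3.52, Hells at 0.84, Bub1 at 8.95, Inhba at -0.43, the Leydig S phase median at 0.067 and that dissociation median at -0.40. Counts that the subtraction all but removes from a library give large ratios, so the size of the largest of these should not be read. At the measured share, Sertoli cells had Dnajb1 at -0.86, Hspa1b at -1.20, Nqo1 at -0.063, Hells at 0.49, Bub1 at 1.45, Cyp26b1 and Inhba at -0.28, and an oxidative stress median of -0.0043. Without the cluster led by cell cycle genes, Knl1 in Sertoli cells was at -0.065.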

Other observations

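Every alternative named here was planned, and no explanation was tested.

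Other somatic classes differed between the libraries in their own ways. Peritubular myoid cells had lower S phase and G2 and mitosis genes (medians -0.33 and -0.39, 22 of 24 and 25 of 26 lower), which became 0.05 with 10% free RNA subtracted and -0.05 with doublets kept, and lower nuclear oxidative phosphorylation genes (-0.26), with Ndufa4 at -0.59. Of their proteasome genes 30 of 32 were lower, led by Psmb3 at -0.67, while the metallothionein Mt1 was at 1.49, on 335 and 942 CPM. Interstitial stromal cells went the other way for division, with 23 of 24 S phase and 24 of 26 G2 and mitosis genes higher (medians 0.30 and 0.28, Cenpe at 0.64 and Aurkb at 0.62), and had Cdkn1a at -1.15. With doublets kept, where the cells were also clustered and named anew, those medians were -0.01 and -0.22, with Cenpe at -0.22. The direction therefore depends on that setting. In Leydig cells steroid synthesis genes had a median of 0.10, inside a random range of -0.10 to 0.12 but 0.37 and above it with each library clustered alone, with Hsd17b3, which makes testosterone, at 1.52 and Akr1c14 at -1.22. Macrophages had Isg15 at 1.01, Il1b at 0.71 and Ifit3 at -1.03. Endothelial cells had higher genes of the unfolded protein response (median 0.41, 14 of 16), but 0.10 at 2000 UMIs and 1000 genes.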
